A study of Mus musculus with 9 samples.

How the data were processed

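Gene expression was measured in C57BL/6 mouse cells on 9 single-colour Illumina arrays. The arrays fall into 3 groups of 3: cultured spermatogonial stem cells (SSC), putative female germ cells (PFGC) and oocytes, and the sample titles say that PFGC and oocytes were collected by magnetic sorting. The labels give neither the antibody of the sort nor the age or tissue of origin. RNA was prepared with Trizol and an RNeasy column with DNase treatment, and biotin-labelled cRNA was made with an Ambion kit, per the labels' protocols. Each array carries a replicate number, but the labels do not say whether replicates came from separate cultures or animals, so p-values measure only the spread between samples that may be technical.

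The authors used GenomeStudio, per the submitters' processing notes, and its version is not given in the sources used here. The deposited table of non-normalized values holds 1 signal intensity and 1 detection p-value per probe and array, per the file headers. These signals were linear, with a lowest value between 73.5 and 84.6 and a highest between 32283 and 43169 on the 9 arrays, and detection p-values moved in steps of 1 over 936. A second table holds the authors' processed intensity for the same arrays. Its values were linear and not centred, every column had a median of 112, and the rank correlation with the non-normalized signal was 1.00 on each array; the shared distribution is that of quantile normalization, although no source used here states it. The main analysis started from the non-normalized intensity, and the processed intensity served as an alternative.

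Probe symbols came from the platform annotation. Of 45281 probes, 34885 carried 1 gene symbol, 18 carried several and 10378 were unnamed here. Symbols were brought up to date through Entrez identifiers in a RefSeq gene table for assembly GRCm38.p6, which matched 34807 named probes (99.7%) and was used for names and chromosomes only. No probe sequence was aligned, so probes of near-identical genes (the Prl2c, Omt2, Fbxw, Stfa, S100a, Hba and Hbb families among them) may report each other's transcripts. No named probe stood for Ddx3y, H19 or Zfp57.

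Background was corrected in limma 3.58.1 (R 4.3.3) by the normal-exponential model, with the negative-control level inferred from the detection p-values and an offset of 16. Arrays were then quantile normalized and values taken to log2. A probe was kept when its detection p was under 0.01 on at least 3 of the 9 arrays, which left 19934 probes, 17171 of them with 1 symbol. Each gene was represented by its kept probe with the highest mean over the 9 arrays, giving 11077 genes, of which 4212 had more than 1 kept probe. Fold changes, and the ranking by them, are those of this brightest probe, and other probes of a gene often gave smaller ones. Levels are log2 values of this scale with their SD over 3 arrays. A level depends on the affinity of the probe as well as on the RNA, so it compares groups within a probe rather than genes with each other.

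All 9 arrays entered 1 limma fit with the 3 groups as terms (lmFit and eBayes, two-sided), and the 3 differences between groups were tested. A gene was called when its p, adjusted by Benjamini-Hochberg over all 11077 genes, was under 0.05; fold sizes of at least 2 were counted after the test. The median standard error of a log2 fold change was 0.15, and the number of arrays limits the precision. Where a probe was detected on no array of the dimmer group, the difference is given as "at least N-fold". This bound sets the brighter group's mean against the dimmer group's mean of, on each array, the probe's own value or the lowest normalized value of any detected probe, whichever was higher.

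The comparisons, the alternatives, 34 gene lists and the rule for naming genes were fixed before the data were examined. The rule takes, per comparison, the 10 largest called changes in each direction among genes whose arrays of the 2 groups did not overlap (leaving out clone and model names), up to 4 called members of each list by size of change, and a fixed set of germ-cell genes. Genes named outside the rule are said to have been chosen after their values were seen. Among 82 named genes with more than 1 kept probe, 20 had probes on both sides of 0 in some comparison, and Ccng1, Cyp11a1, Ddx4, Itga6, Kit and Tbx3 had probes more than 0.5 log2 units away from 0 on both sides.

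Germ-cell lists covered undifferentiated spermatogonia, differentiating spermatogonia, meiotic prophase, germ cell identity shared by both sexes, spermatids and postmeiotic genes, oocyte genes, early follicle and oogenesis regulators, pluripotency and primordial germ cells. Lists for other cells covered granulosa and cumulus cells, steroidogenic cells, Sertoli cells, fibroblasts with myoid and feeder cells, macrophages and leukocytes, endothelial cells, erythrocytes and epithelial cells. Lists for sex and imprinting covered the female and male pathways of gonad and germ cell, Y-linked genes, X-linked partners of Y genes with Xist, maternally and paternally expressed imprinted genes, and DNA methylation with imprint maintenance. Lists for processes covered the cell cycle, p53 response, immediate early genes with dissociation stress, interferon response, retinoic acid response, glycolysis, the mitochondrial respiratory chain, cytoplasmic ribosomal proteins, cholesterol synthesis, and extracellular matrix receptors with junctions. Each list of at least 5 measured genes was tested against the other genes with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 34 lists, and again with an estimated correlation. List p-values below are camera's adjusted p, counts of members come from the gene-wise limma test over all genes, and a second count is adjusted over the list alone.

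The place of each PFGC array between SSC and oocyte was the slope, through 0, of its difference from the SSC mean on the difference between the oocyte and SSC means, over the genes called at 2-fold or more between oocyte and SSC; 0 is the SSC level and 1 the oocyte level. Fold changes of PFGC and oocyte share the SSC arrays, so their correlation and overlap were set beside 100 simulations of unchanged groups against the same SSC arrays. A share of SSC signal in PFGC was computed on the linear scale, with the oocyte level subtracted, for genes called at least 8-fold higher in SSC than in oocyte, and for list members and all genes called at least 2-fold higher. The share of the spermatid list was set beside 10000 random sets matched on the fold between SSC and oocyte. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

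Whether replicate numbers pair arrays across groups was checked by correlating deviations from the group means. All 9 pairs of arrays with the same number in different groups correlated above 0.1, from 0.131 to 0.575, and the 3 pairs of arrays numbered 3 gave 0.403 to 0.575; the 18 pairs with different numbers gave -0.442 to 0.246. Pairs numbered 3 lay above the range of different numbers. Pairs numbered 1 or 2 lay within it, except PFGC and oocyte replicates 1 (0.316). Deviations of 3 arrays from their mean sum to 0. A deviation shared by the arrays numbered 3 alone therefore raises the correlations among arrays numbered 1 and 2, whether or not their numbers match. These values thus show arrays numbered 3 deviating together, and do not show a pairing of arrays numbered 1 or 2. The labels state no pairing, so the main fit had no block, and a block by replicate number served as an alternative.

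Alternatives were no background correction, an offset of 50, no normalization, scaling to the 75th percentile, cyclic loess, the authors' processed intensity, no filter on dim probes, detection on all 9 arrays, the mean of a gene's probes, the replicate block, fits of only the 2 groups compared, eBayes with trend and robust settings, array weights, limma's fry in place of camera, and each array left out in turn. Leaving out the arrays numbered 3 from every group was added after seeing the data, because these arrays deviated together.

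The fit, the list test, the position and the share were tested on simulated gene-level values. Noise was independent between genes, so correlation within lists was not simulated, and a list call in the data is less certain than here. Background correction, normalization and probe choice were not simulated either. For the fit, 50 genes were changed at each of 4 sizes among 11077. Of genes changed 1.5-fold, 22% were recovered for PFGC versus SSC, 40% for oocyte versus SSC and 36% for PFGC versus oocyte. At 2-fold the recovered shares were 90%, 86% and 82%, and at 4-fold and 8-fold 100% in each comparison. False calls made up 15 of 171, 9 of 172 and 10 of 169 calls in the same order. A planted list was called in each comparison and 0 of 20 random lists were called by camera; a simulated position of 0.75 was measured as 0.748, and a simulated share of 15% as 14.2%.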

Results

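Transcripts were profiled in 3 arrays each of cultured mouse spermatogonial stem cells (SSC), of cells labelled putative female germ cells (PFGC) and of oocytes. SSC are the self-renewing germ cells of the testis, and the series title frames PFGC as cells obtained from them. Between 17631 and 18919 of the 45281 probes (38.9% to 41.8%) were detected per array, with a median signal of 104 to 122. Across the 11077 genes tested, PFGC arrays correlated with oocyte arrays at r = 0.956 to 0.972 and with SSC arrays at 0.858 to 0.888, while SSC and oocyte arrays correlated at 0.801 to 0.825. These are correlations across genes, which are not independent replicates. Within groups r ranged from 0.973 to 0.986 in SSC, 0.986 to 0.993 in PFGC and 0.988 to 0.995 in oocytes. No pair of replicates held identical values over the array, and the median absolute log2 difference between replicates ran from 0.12 (oocyte replicates 1 and 2) to 0.26 (SSC replicates 2 and 3).

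The first comparison, PFGC against SSC, asks how the putative female cells differ from the stem cells they are said to come from. PFGC carried oocyte transcripts that were low or not detected in SSC. Figla, a transcription factor that activates zona pellucida genes, had a log2 level of 10.09 ± 0.35 (SD, n = 3) in PFGC and was at least 28.3-fold higher than in SSC (adjusted p = 4.42e-09). Gdf9, a growth factor secreted by oocytes, stood at 10.81 ± 0.31 in PFGC and 5.78 ± 0.45 in SSC, a 32.7-fold difference (log2 fold change 5.03, SE 0.23). The oocyte homeobox gene Nobox was 22.1-fold higher (4.47, SE 0.28). In the other direction, Gfra1, the receptor through which GDNF maintains spermatogonial stem cells, was 7.04-fold lower in PFGC (log2 fold change -2.82, SE 0.19), and its co-receptor Ret was 6.11-fold lower.

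Largest among the increases were Cxcl10, an interferon-induced chemokine, at 316-fold (log2 fold change 8.31, SE 0.13), and Pramel25 of the Prame family, at least 206-fold. The maternal gene Omt2a (at least 109-fold), the prolactin-family genes Prl2c3 (at least 106-fold) and Prl2c2 (at least 101-fold) and Elobl (at least 106-fold) followed. Next came Cdkn1a, which encodes the cell cycle inhibitor p21 (at least 105-fold), Oas1d, an oocyte member of the oligoadenylate synthetase family (at least 98.5-fold), Fbxw15 (at least 83.8-fold) and Omt2b (at least 81.1-fold). Other kept probes gave smaller increases, with log2 fold changes of 2.19 for Cxcl10, 3.18 for Pramel25, 2.83 for Omt2b, 3.67 for Cdkn1a and 5.43 for Oas1d. The largest decreases were smaller. Nt5e, which encodes the ectonucleotidase CD73, was 9.59-fold lower (log2 fold change -3.26, SE 0.16), followed by Rasgef1c (8.91-fold), the Sertoli-cell homeobox gene Rhox8 (8.87-fold) and the Y-linked gene Usp9y (8.71-fold). Ttyh1 (8.64-fold), Hsd17b3, the testicular enzyme that completes testosterone (8.45-fold), Rarres1 (8.33-fold), Qpct (8.10-fold), Lrp4 (8.04-fold) and Wipf3 (8.01-fold) were close behind. Adjusted p-values of these 20 genes were between 4.01e-11 and 6.59e-05.

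Oocyte genes rose as a group: 48 of 55 measured members were higher in PFGC, 2 were lower and 5 were not called, with the same counts when adjusted over the list alone. Their median log2 fold change was 4.03 (adjusted p = 8.52e-26, and adjusted p = 0.00225 with an estimated correlation). Besides the Omt2 genes and Oas1d, Zp3, a zona pellucida glycoprotein, was at least 3.38-fold higher (adjusted p = 2.92e-07). Regulators of the early follicle were higher in 14 of 22, with 5 lower, also when adjusted over the list alone (adjusted p = 0.00227, and adjusted p = 0.0965 with an estimated correlation). Bmp15, an oocyte growth factor, was at least 34.9-fold higher. Dppa3, a maternal factor that protects the egg's DNA methylation, rose 80.5-fold (log2 level 11.91 ± 0.16 against 5.58 ± 0.36, n = 3).

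Genes of undifferentiated spermatogonia fell: 21 of 29 were lower and 5 higher, with the same counts adjusted over the list alone. The median log2 fold change was -1.08 (adjusted p = 2.61e-04, and adjusted p = 0.165 with an estimated correlation). Zbtb16, a transcription factor of stem cell maintenance, was 4.54-fold lower (adjusted p = 2.93e-06). Id4, a marker of the stem cell fraction, was 1.54-fold lower (adjusted p = 0.0248). That call ended without PFGC replicate 1 (adjusted p = 0.0536), PFGC replicate 3 (0.0835), SSC replicate 2 (0.0695) or SSC replicate 3 (0.0827), and under other settings with adjusted p from 0.0647 to 0.136. Itga6, a surface integrin used to enrich stem cells, was 6.16-fold lower through the brightest probe. Another of its probes gave a log2 fold change of 0.70 among genes detected on all arrays, so its direction depends on the probe.

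Meiotic prophase genes were lower in 17 of 25 and higher in 4 (18 lower when adjusted over the list alone; adjusted p = 0.00227, and adjusted p = 0.173 with an estimated correlation). Members went apart: Tex11, needed for recombination, was 6.59-fold lower, Meioc 5.12-fold lower, and Stra8, which marks entry into meiosis, had a log2 fold change of -2.32 (adjusted p = 1.75e-06), whereas Sycp1 was at least 18.7-fold and Sycp3 3.48-fold higher, both of them parts of the synaptonemal complex. Shared germ cell genes (7 of 31 higher, 17 lower, 8 and 17 when adjusted over the list alone; adjusted p = 0.137) and genes of differentiating spermatogonia (5 of 15 higher, 9 lower, also over the list alone; adjusted p = 0.257) were not called as lists. The RNA-binding gene Dazl was 4.73-fold lower. The helicase gene Ddx4 was 5.43-fold higher through a probe at log2 2.44, while its least favourable probe gave -0.97. Kit was at least 4.78-fold higher, with probes between -0.85 and 2.79.

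Pluripotency genes split evenly, with 9 of 20 higher and 11 lower, also when adjusted over the list alone (median log2 fold change -0.91, mean 0.40, adjusted p = 0.939). Pou5f1 was 3.16-fold lower and Dppa5a 17.2-fold higher. Among primordial germ cell genes 11 of 19 were higher and 7 lower (12 higher adjusted over the list alone; adjusted p = 0.0653), including Ifitm3, a membrane protein of early germ cells, at 7.50-fold higher. Of 15 spermatid genes, 1 was higher and 2 were lower (0 and 2 adjusted over the list alone; adjusted p = 0.939). SSC replicate 2 stood apart in this list: without it 7 of 14 members were higher and 1 lower (adjusted p = 0.0211). Ldhc, a lactate dehydrogenase of spermatocytes, had log2 levels of 5.92, 12.96 and 5.83 in SSC replicates 1 to 3, against 12.31 ± 0.23 (n = 3) in PFGC. Its log2 fold change of 4.07 (adjusted p = 0.0437) became 6.44 without SSC replicate 2, and the call was lost when any other single array was left out, with adjusted p from 0.0549 to 0.160.

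Besides the oocyte genes, the granulosa and endothelial lists were called higher in PFGC at the preset correlation, but not with an estimated one. The epithelial and steroidogenic lists were not called. Granulosa and cumulus genes were higher in 20 of 24 and lower in 3, also when adjusted over the list alone. Their mean log2 level was 8.70 against 6.83 (adjusted p = 1.22e-06, and adjusted p = 0.0915 with an estimated correlation). Nr5a2, a nuclear receptor of granulosa cells, was at least 33.8-fold higher, and the estrogen receptor gene Esr2 at least 15.5-fold. Bmpr1b was at least 10.4-fold and Fst, the activin-binding follistatin, at least 8.19-fold higher. Among 3 kept probes each, the lowest log2 fold change was 0.58 for Nr5a2 and 1.83 for Esr2. Endothelial genes were higher in 15 of 19 and lower in 1, also over the list alone (adjusted p = 1.37e-04, and adjusted p = 0.148 with an estimated correlation). They were led by Icam2 (at least 14.7-fold), Emcn (7.17-fold) and Cldn5 (4.88-fold). Epithelial genes (10 of 18 higher, 5 lower, 11 and 5 when adjusted over the list alone; adjusted p = 0.0653) included the keratin gene Krt8, 15.2-fold higher, and Epcam, 7.95-fold lower. Steroidogenic genes (6 of 10 higher, 3 lower, also over the list alone; adjusted p = 0.0669) included Cyp17a1, a steroid hydroxylase, at least 3.73-fold higher.

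Sertoli cell genes fell in 15 of 23 and were higher in 3, also when adjusted over the list alone. Their median log2 fold change was -1.40 (adjusted p = 2.61e-04, and adjusted p = 0.0915 with an estimated correlation). Besides Rhox8, the signalling gene Dhh was 6.26-fold and Cst9 5.46-fold lower. Among erythrocyte genes 5 of 9 were higher and 0 lower by limma, also over the list alone (adjusted p = 0.0345, and adjusted p = 0.222 with an estimated correlation). Macrophage genes (6 of 21 higher, 3 lower, also over the list alone; median log2 fold change -0.01, mean 0.26, adjusted p = 0.513) and fibroblast genes (13 of 40 higher, 9 lower, 14 and 9 over the list alone; adjusted p = 0.189) were not called. Cd14 of the first list was 5.58-fold and Thbs1 of the second 8.45-fold higher.

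Transcripts of the Y chromosome fell and Xist, which coats the inactive X, rose. All 5 Y-linked genes measured were lower, also when adjusted over the list alone (adjusted p = 0.00427, and adjusted p = 0.165 with an estimated correlation): Eif2s3y stood at a log2 level of 5.86 ± 0.12 in PFGC and 8.59 ± 0.37 in SSC (n = 3, 6.63-fold), and Xist was 13.6-fold higher (log2 fold change 3.77, SE 0.17). The X-linked partners were not called as a list (5 of 9 higher, 1 lower, 5 and 2 over the list alone; adjusted p = 0.113). Ddx3x was 2.90-fold and Eif2s3x 2.50-fold higher and Sox3 5.35-fold lower. Female pathway genes were higher in 12 of 18 and lower in 2, also over the list alone (adjusted p = 0.00227, and adjusted p = 0.148 with an estimated correlation). The transcription factor genes Irx3 (17.7-fold) and Runx1 (at least 5.83-fold) were among them, although another kept probe of Runx1 gave a log2 fold change of 0.51. Male pathway genes were lower in 10 of 12 and higher in 1, or 2 when adjusted over the list alone (adjusted p = 0.00227, and adjusted p = 0.0915 with an estimated correlation). Sox8 was 4.51-fold lower and Dnmt3l 5.13-fold higher.

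Interferon response genes rose in 23 of 25 with 0 lower by limma, also when adjusted over the list alone. Their median log2 fold change was 1.96 (adjusted p = 9.14e-14, and adjusted p = 0.0356 with an estimated correlation). Besides Cxcl10, the antiviral genes Rsad2 (104-fold), Usp18 (65.4-fold) and Ifit3 (55.8-fold) led. Genes of the p53 response were higher in 12 of 19 and lower in 2, or 3 over the list alone (adjusted p = 0.00227, and adjusted p = 0.0915 with an estimated correlation). The death receptor gene Fas was 7.53-fold higher, with log2 fold changes down to 0.54 from its other kept probes. Immediate early and dissociation stress genes were higher in 16 of 24 and lower in 2 (17 higher over the list alone; adjusted p = 7.51e-04, and adjusted p = 0.0647 with an estimated correlation). Ier3 (6.07-fold) and the heat shock gene Hspa1a (4.28-fold) were among them. Ribosomal protein genes rose in 15 of 50 with 0 lower by limma, also over the list alone (median log2 fold change 0.18, adjusted p = 0.00427, and adjusted p = 0.0748 with an estimated correlation). Rpl4 rose by 2.53-fold. Matrix receptor and junction genes were higher in 12 of 28 and lower in 5, also over the list alone (adjusted p = 0.0473, and adjusted p = 0.222 with an estimated correlation). Gja4, the connexin of oocyte junctions, was 12.1-fold higher.

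Imprinted genes were called as a list neither for the maternally expressed (3 of 12 higher, 4 lower, 3 and 5 over the list alone; adjusted p = 0.513) nor for the paternally expressed (3 of 17 higher, 9 lower, also over the list alone; adjusted p = 0.256). Dlk1, a paternally expressed Notch ligand, was 4.57-fold and the growth factor gene Igf2 4.38-fold lower. Genes of DNA methylation and imprint maintenance (8 of 18 higher, 4 lower, also over the list alone; adjusted p = 0.236) were not called, and the methyltransferase gene Dnmt3b was 3.58-fold lower. Cell cycle genes (6 of 33 higher, 13 lower, 7 and 14 over the list alone; adjusted p = 0.338), retinoic acid genes (4 of 17 higher, 7 lower, 4 and 8 over the list alone; adjusted p = 0.472) and cholesterol synthesis genes (3 of 17 higher, 7 lower, also over the list alone; adjusted p = 0.577) were not called. Neither were glycolysis genes (6 of 19 higher, 4 lower, also over the list alone; adjusted p = 0.219) and respiratory chain genes (4 of 52 higher, 6 lower, 1 and 4 over the list alone; adjusted p = 0.513). The replication gene Mcm2 was 2.02-fold and the retinoic acid binding gene Crabp1 3.94-fold lower.

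In all, 5770 of 11077 genes (52.1%) were called, 2709 higher and 3061 lower in PFGC. Of them, 2181 differed at least 2-fold (1241 higher, 940 lower). Of 34 lists, 16 were called, and the oocyte and interferon lists held with an estimated correlation. The matrix list was lost with the replicate block (adjusted p = 0.0852), and without PFGC replicate 1 (0.0522) or oocyte replicate 3 (0.0505). It was also lost with 75th percentile scaling (0.0526), cyclic loess (0.0587), the mean of probes (0.0543) or only the 2 groups fitted (0.0516). The erythrocyte list was lost without SSC replicate 3 (0.0589), with array weights (0.0594) or without the arrays numbered 3 (0.0603). Among genes detected on all 9 arrays, the lists of undifferentiated spermatogonia (adjusted p = 0.105), meiotic prophase (0.124), early follicle (0.123), erythrocytes (0.0730) and the male pathway (0.105) were no longer called. Lists without a call gained one in single alternatives: primordial germ cells without normalization (adjusted p = 0.0194), with no filter on dim probes (0.0239) or with trend and robust settings (0.0495), and steroidogenic genes with no filter (0.0254). Epithelial genes did so without normalization (0.0324) or SSC replicate 1 (0.0390), X-linked partners (0.000982) and glycolysis (0.0411) among genes detected on all 9 arrays, and fibroblast genes without the arrays numbered 3 (0.0401).

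The second comparison sets the magnetically sorted oocytes against the cultured SSC. Handling therefore cannot be told apart from cell type here, as in the comparison of PFGC with SSC. Oocyte arrays carried the egg transcripts: Gdf9 stood at a log2 level of 11.68 ± 0.14 (SD, n = 3) and was 59.6-fold higher than in SSC (log2 fold change 5.90, SE 0.23). Figla was at least 47.5-fold higher (adjusted p = 1.45e-09) and Dppa3 57.5-fold. Transcripts of testicular cells were lower. Defb36, a defensin of the Sertoli list, fell from 13.28 ± 0.13 in SSC to a level not detected in oocytes, at least 269-fold. Taf7l, a transcription factor of spermatogenic cells, was 143-fold lower (log2 fold change -7.16, SE 0.27). Eif2s3y was not detected in oocytes and was at least 10.4-fold lower, while Xist was 18.0-fold higher.

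Among the 10 largest increases were Cxcl10 (361-fold), Pramel25 (at least 228-fold), Cdkn1a (at least 135-fold), Elobl (at least 118-fold) and Omt2a (at least 114-fold). The others were Oas1d (at least 105-fold), Padi6, a component of the egg's cytoplasmic lattices (at least 96.4-fold), the survival gene Bcl2l10 (at least 94.0-fold), Omt2b (at least 89.7-fold) and Fbxw15 (at least 83.9-fold). Here too the other kept probes gave less, with log2 fold changes of 3.40 for Cxcl10, 3.47 for Pramel25 and 3.06 for Omt2b. The largest decreases after Defb36 were Cst9 (228-fold), Taf7l, Usp26 (at least 81.5-fold), Tuba3b (74.9-fold) and Slc52a3 (64.3-fold), then the synaptonemal complex gene Syce3 (at least 56.3-fold), Cstdc1 (at least 47.6-fold), Rarres1 (at least 39.5-fold) and the germ-cell homeobox gene Rhox13 (at least 32.7-fold). Adjusted p-values of these 20 genes were between 3.56e-11 and 3.29e-08. Another kept probe of Usp26 gave a log2 fold change of -1.66.

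Oocyte genes were higher in 48 of 55 and lower in 2, also when adjusted over the list alone. The median log2 fold change was 4.13 (adjusted p = 9.25e-22, and adjusted p = 0.00366 with an estimated correlation), and Zp3 was at least 5.98-fold higher. Early follicle genes (14 of 22 higher, 5 lower, also over the list alone; adjusted p = 0.00673, and adjusted p = 0.131 with an estimated correlation) included Bmp15 (at least 54.7-fold) and Nobox (33.7-fold). Undifferentiated spermatogonia genes were lower in 21 of 29 and higher in 5, also over the list alone (median log2 fold change -1.33, adjusted p = 3.35e-04, and adjusted p = 0.166 with an estimated correlation). Gfra1 was at least 11.9-fold, Ret 13.5-fold and Zbtb16 5.82-fold lower. Id4 was 1.49-fold lower (adjusted p = 0.0307), a call that ended without SSC replicate 2 (adjusted p = 0.0848), SSC replicate 3 (0.102), oocyte replicate 1 (0.0817) or oocyte replicate 2 (0.112), and under other settings with adjusted p from 0.0758 to 0.103. Meiotic prophase genes were lower in 19 of 25 and higher in 3, also over the list alone (median log2 fold change -1.70, adjusted p = 2.25e-04, and adjusted p = 0.132 with an estimated correlation). Stag3, a meiotic cohesin, was 44.6-fold and Stra8 at least 5.12-fold lower, whereas Sycp1 was at least 20.9-fold and Sycp3 6.22-fold higher. Shared germ cell genes fell in 18 of 31 and were higher in 6 (19 lower over the list alone; adjusted p = 0.00837, and adjusted p = 0.402 with an estimated correlation). Dazl fell by 10.5-fold and Tex101 by at least 29.0-fold, while Ddx4 was 5.75-fold higher.

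Spermatid genes were lower in 8 of 15 with 0 higher by limma, also over the list alone (median log2 fold change -0.87, adjusted p = 0.0227, and adjusted p = 0.421 with an estimated correlation). Without SSC replicate 2 the list was not called (adjusted p = 0.0893). Clgn, a testis chaperone of this list, was at least 9.39-fold lower, and without SSC replicate 2 its log2 fold change was -3.61 (adjusted p = 4.72e-07). Genes of differentiating spermatogonia (5 of 15 higher, 9 lower, also over the list alone; adjusted p = 0.171) and of primordial germ cells (12 of 19 higher, 7 lower, also over the list alone; adjusted p = 0.0558) were not called. The pluripotency list was not called either (9 of 20 higher, 11 lower, also over the list alone; median -0.74, mean 0.16, adjusted p = 0.811). Pou5f1 was 3.62-fold lower.

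Granulosa genes were higher in 20 of 24 and lower in 4, also when adjusted over the list alone (median log2 fold change 1.94, adjusted p = 5.41e-06, and adjusted p = 0.111 with an estimated correlation). Nr5a2 was at least 43.4-fold and Esr2 at least 21.8-fold higher, with log2 fold changes down to 1.20 and 2.21 from other kept probes. Endothelial genes rose in 15 of 19 with 1 lower (16 and 2 over the list alone; adjusted p = 3.66e-05, and adjusted p = 0.131 with an estimated correlation). Icam2 was at least 26.3-fold and Emcn 12.8-fold higher. Macrophage genes were higher in 12 of 21 and lower in 2, also over the list alone (adjusted p = 0.0149, and adjusted p = 0.185 with an estimated correlation). Erythrocyte genes were higher in 7 of 9 with 0 lower by limma, also over the list alone (adjusted p = 0.0147, and adjusted p = 0.185 with an estimated correlation). Cd14 was 9.43-fold and the band 3 gene Slc4a1 4.11-fold higher. Sertoli genes were lower in 17 of 23 and higher in 4, also over the list alone. Their median log2 fold change was -2.27 (adjusted p = 5.64e-05, and adjusted p = 0.0981 with an estimated correlation). Rhox8 was 59.0-fold and the tight junction gene Cldn11 36.4-fold lower.

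Female pathway genes were higher in 12 of 18 and lower in 2 (adjusted p = 0.00112, and adjusted p = 0.131 with an estimated correlation). Male pathway genes were lower in 10 of 12 and higher in 2 (adjusted p = 0.00288, and adjusted p = 0.114 with an estimated correlation). All 5 Y-linked genes were lower (adjusted p = 0.00837, and adjusted p = 0.166 with an estimated correlation), and these lists kept their counts adjusted over the list alone. Irx3 was 26.8-fold higher and the male regulator Nanos2 9.80-fold lower. Interferon genes rose in 24 of 25 with 0 lower by limma, also over the list alone (median log2 fold change 2.73, adjusted p = 2.38e-13, and adjusted p = 0.0385 with an estimated correlation). Usp18 rose by 132-fold. Genes of the p53 response were higher in 13 of 19 and lower in 5, also over the list alone (adjusted p = 0.0177, and adjusted p = 0.156 with an estimated correlation). Immediate early genes were higher in 17 of 24 and lower in 2, also over the list alone (adjusted p = 6.87e-04, and adjusted p = 0.0656 with an estimated correlation). Respiratory chain genes were lower in 24 of 52 and higher in 2 (22 and 2 over the list alone; median log2 fold change -0.33, adjusted p = 0.0119, and adjusted p = 0.335 with an estimated correlation). Cycs, the electron carrier cytochrome c, fell by 1.92-fold. Ribosomal protein genes were higher in 16 of 50 and lower in 2 (15 and 0 over the list alone by limma; adjusted p = 0.0119, and adjusted p = 0.0981 with an estimated correlation). Matrix receptor genes were higher in 12 of 28 and lower in 5, also over the list alone (adjusted p = 0.0248, and adjusted p = 0.185 with an estimated correlation). The X-linked partners passed with 6 of 9 higher and 1 lower, also over the list alone (adjusted p = 0.0419, and adjusted p = 0.156 with an estimated correlation).

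Cell cycle genes (6 of 33 higher, 16 lower, 6 and 17 over the list alone; adjusted p = 0.0634) and steroidogenic genes (7 of 10 higher, 3 lower, also over the list alone; adjusted p = 0.0514) were not called. The steroidogenic list was called without SSC replicate 1 (adjusted p = 0.0474) or oocyte replicate 2 (0.0468), and the cell cycle list without SSC replicate 2 (0.0358). The primordial germ cell list was called without SSC replicate 1 (0.0487). All 3 lists were also called with no background correction (adjusted p = 0.0478 for steroidogenic, 0.0498 for cell cycle and 0.0434 for primordial germ cell genes), with the authors' values (0.0480, 0.0497 and 0.0437), with no filter on dim probes (0.0120, 0.0120 and 0.0206) and among genes detected on all 9 arrays (0.0434, 0.0446 and 0.0446). The steroidogenic and primordial germ cell lists were called with an offset of 50 (0.0455 and 0.0438) and with trend and robust settings (0.0471 and 0.0447), so these absences of a call depend on the setting.

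Over all genes, 6831 (61.7%) were called, 3166 higher and 3665 lower in oocytes, with 3135 at least 2-fold apart (1619 higher, 1516 lower). Without normalization between arrays 57.2% of calls were higher, against 46.3%. For Id4 the arrays of SSC and oocytes overlapped. The X-linked list was lost without SSC replicate 2 (adjusted p = 0.0519) or SSC replicate 3 (0.0536), without normalization (0.0657) and with the mean of probes (0.0542), which also ended the p53 call (0.101). The respiratory chain call ended without normalization (0.113). Among genes detected on all 9 arrays the lists of undifferentiated spermatogonia (adjusted p = 0.0953), early follicle (0.160) and the male pathway (0.0775) were not called.

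**Figure D1:**
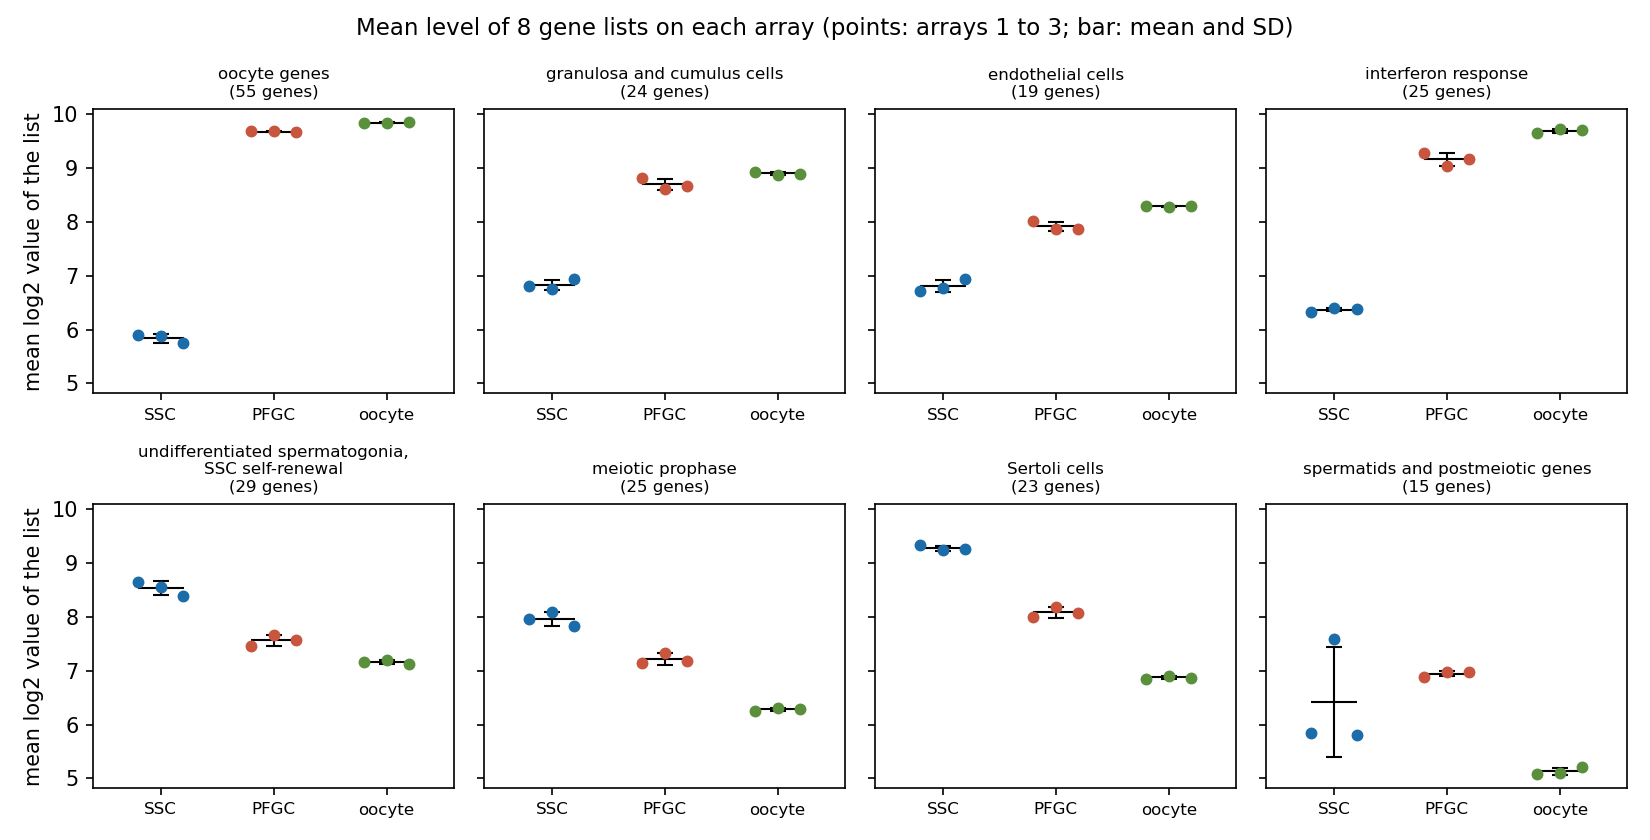
Mean log2 value of 8 gene lists on each of the 9 arrays, 1 panel per list with the number of measured genes. Points are arrays, horizontal bars the group mean and error bars the SD (n = 3). In the oocyte and interferon panels the PFGC points lie close to the oocyte points, in the Sertoli and meiotic panels they lie between the other groups, and in the spermatid panel SSC replicate 2 lies above all other arrays.

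The third comparison, PFGC against oocytes, asks what still separates the putative female cells from oocytes. PFGC carried signals of testis genes that were low or not detected in oocytes. Syce3 had a log2 level of 10.54 ± 0.13 (SD, n = 3) in PFGC and was at least 40.3-fold higher than in oocytes (adjusted p = 2.19e-06). The Sertoli gene Defb36 was at least 56.5-fold and Cst9 41.8-fold higher. The Y-linked Eif2s3y was detected in PFGC at 5.86 ± 0.12, at least 1.57-fold above oocytes (adjusted p = 0.00039). Differences in oocyte genes were small. Figla was 1.68-fold and Gdf9 1.83-fold lower in PFGC, and Dppa3 had a log2 fold change of 0.48 (SE 0.17, adjusted p = 0.0986).

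Among the 10 largest increases in PFGC were the prolactin-family genes Prl2c2 (90.2-fold), Prl2c4 (83.8-fold) and Prl2c3 (82.3-fold), Fabp9, a fatty acid binding protein of spermatids (at least 76.1-fold, adjusted p = 0.00939), and Defb36. The others were Cox8c, a testis subunit of cytochrome c oxidase (at least 51.8-fold), Cst9, Syce3, Tuba3b (28.7-fold) and Tcte3 (28.5-fold, adjusted p = 0.00543). Prl2c2 reached a log2 level of 11.94 ± 0.25 (n = 3) in PFGC, against 4.40 in SSC and 5.44 in oocytes. Lower in PFGC were the cystatin-family genes Stfa1 (10.9-fold), Stfa2 (6.46-fold) and Cstdc4 (5.41-fold). So were the neutrophil granule genes Ngp (at least 3.32-fold), S100a9 (4.08-fold), Camp (3.80-fold) and Retnlg (at least 2.22-fold), with Slc4a1 of erythrocytes (3.45-fold) and the steroid enzyme gene Akr1c18 (2.77-fold). S100a8 was 3.89-fold lower (adjusted p = 0.0146), a call lost without PFGC replicate 3 (adjusted p = 0.0501), oocyte replicate 1 (0.0524) or oocyte replicate 2 (0.0547).

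Lists of meiotic, shared germ cell, spermatid and spermatogonial genes were called higher in PFGC at the preset correlation. None of them held with an estimated correlation. Meiotic prophase genes were higher in 10 of 25 and lower in 1 (13 and 2 when adjusted over the list alone; adjusted p = 1.77e-06, and adjusted p = 0.150 with an estimated correlation). They included Stag3 (9.37-fold) and Spo11, which makes meiotic DNA breaks (at least 3.63-fold). Sycp3 was 1.79-fold lower. Shared germ cell genes rose in 15 of 31 with 1 lower (19 and 1 over the list alone; median log2 fold change 0.77, adjusted p = 1.26e-07, and adjusted p = 0.190 with an estimated correlation). Among them were Tex101 (at least 12.1-fold) and the piRNA helicase gene Mov10l1 (4.47-fold). Spermatid genes were higher in 6 of 15 with 0 lower by limma (12 and 0 over the list alone; median log2 fold change 1.40, adjusted p = 7.91e-06, and adjusted p = 0.194 with an estimated correlation), among them Clgn (at least 8.29-fold). With SSC replicate 2 left out of the pooled spread, 11 of 14 were higher. Piwil1, a PIWI gene of piRNA synthesis, was 17.2-fold higher (adjusted p = 0.0112). Without SSC replicate 2 its adjusted p = 7.42e-07, and that of Fabp9 1.13e-07, of Cox8c 2.25e-08 and of Tcte3 8.36e-07. Undifferentiated spermatogonia genes were higher in 9 of 29 with 0 lower by limma (10 and 2 over the list alone; adjusted p = 0.00290, and adjusted p = 0.266 with an estimated correlation). Gfra1 was at least 1.69-fold and Nanos2 2.59-fold higher. Differentiating spermatogonia genes were higher in 5 of 15 with 1 lower (6 and 1 over the list alone; adjusted p = 0.0138, and adjusted p = 0.190 with an estimated correlation), with Rhox13 at least 7.08-fold higher. Dazl was 2.21-fold higher (adjusted p = 0.00916, and 0.0523 without normalization).

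Oocyte genes were lower as a list, although only 5 of 55 members were called lower and 1 higher, also over the list alone (median log2 fold change -0.15, adjusted p = 0.00314, and adjusted p = 0.171 with an estimated correlation). Zp3 was 1.77-fold lower (adjusted p = 0.00699). The call on Gdf9 (adjusted p = 0.0348) ended without PFGC replicate 2 (0.131) or 3 (0.0862) or oocyte replicate 1 (0.0874), 2 (0.0857) or 3 (0.0940), and with no filter on dim probes (0.0505) or no arrays numbered 3 (0.0951). Figla (adjusted p = 0.0240) was not called without PFGC replicate 2 (0.0580) or 3 (0.0551) or oocyte replicate 1 (0.0957) or 2 (0.0869). Nobox, at -0.61 (adjusted p = 0.187), was called with the replicate block (adjusted p = 0.0380) or without PFGC replicate 1 (0.0477). Early follicle genes (3 of 22 higher, 4 lower, 3 and 6 over the list alone; adjusted p = 0.293) were not called. In this comparison the next 7 genes were not called. Xist differed by -0.40 (SE 0.17, adjusted p = 0.164), Ddx4 by -0.08 (adjusted p = 0.648) and Kit by -0.21 (0.438). The difference was 0.20 for Pou5f1 (adjusted p = 0.453), 0.36 for Zbtb16 (0.196), 0.52 for Stra8 (0.0700) and -0.05 for Id4 (0.894). Other settings called some of these, such as Xist without normalization (adjusted p = 0.0292), Stra8 with 75th percentile scaling (0.0332) and Pou5f1 with the mean of probes (0.00815). Dppa3 was called with no background correction (adjusted p = 0.0110), an offset of 50 (0.0294), the authors' values (0.0127), only the 2 groups fitted (0.0352) or array weights (0.0292), and without SSC replicate 3 (0.0291).

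Sertoli genes were higher in 11 of 23 and lower in 1 (12 and 3 when adjusted over the list alone; median log2 fold change 0.56, adjusted p = 1.07e-06, and adjusted p = 0.127 with an estimated correlation). Rhox5 was 18.3-fold and Cldn11 7.03-fold higher. Endothelial genes were lower in 7 of 19 with 0 higher by limma (9 and 0 over the list alone; adjusted p = 3.11e-05, and adjusted p = 0.174 with an estimated correlation). Emcn and Flt1 fell by 1.79-fold each. Macrophage genes were lower in 8 of 21 with 0 higher by limma (11 and 0 over the list alone; adjusted p = 9.99e-06, and adjusted p = 0.150 with an estimated correlation), the complement gene C1qb by 1.63-fold. Granulosa genes were lower in 4 of 24 and higher in 1, also over the list alone (adjusted p = 0.0282, and adjusted p = 0.317 with an estimated correlation), a call lost without PFGC replicate 2 (adjusted p = 0.0862) or 3 (0.0610). Interferon genes fell in 12 of 25 with 0 higher by limma (17 and 1 over the list alone; median log2 fold change -0.59, adjusted p = 6.67e-08, and adjusted p = 0.127 with an estimated correlation). Ifit3 fell by 2.10-fold. Male pathway genes were higher in 3 of 12 with 0 lower by limma (4 and 0 over the list alone; adjusted p = 0.0138, and adjusted p = 0.174 with an estimated correlation). Female pathway genes were lower in 2 of 18 with 0 higher by limma (5 and 1 over the list alone; adjusted p = 0.0108, and adjusted p = 0.190 with an estimated correlation). The male call was lost with no background correction (adjusted p = 0.0602) and with the authors' values (0.0524).

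Respiratory chain genes were higher in 5 of 52 with 0 lower by limma (10 and 0 over the list alone; median log2 fold change 0.26, adjusted p = 1.85e-05, and adjusted p = 0.190 with an estimated correlation). Cell cycle genes were higher in 6 of 33 with 0 lower by limma, also over the list alone (median 0.18, adjusted p = 0.00290, and adjusted p = 0.171 with an estimated correlation). Without normalization the median of the cell cycle list turned to -0.05 and its call was lost (adjusted p = 0.0575). Immediate early genes were lower as a list with 1 of 24 called (0 over the list alone by limma; adjusted p = 0.0312, and adjusted p = 0.171 with an estimated correlation). The Y-linked (2 of 5 higher, also over the list alone; adjusted p = 0.0866), erythrocyte (2 of 9 lower, 2 lower and 1 higher over the list alone; adjusted p = 0.109) and steroidogenic lists (4 of 10 lower, 1 higher, 4 and 2 over the list alone; adjusted p = 0.104) were not called. The Y-linked list was called without normalization (adjusted p = 0.00590), with 75th percentile scaling (0.0298) or cyclic loess (0.0431) and without oocyte replicate 1 (0.0478). The erythrocyte list was called with the mean of probes (0.0394) or detection on all 9 arrays (0.0466), and the steroidogenic list with no background correction (0.0469), no filter on dim probes (0.0460) or detection on all 9 arrays (0.0398). Matrix receptor genes (adjusted p = 0.120) were called with no filter (0.0426), detection on all 9 arrays (0.0166) or without SSC replicate 2 (0.0391) or 3 (0.0447), and X-linked partners (adjusted p = 0.174) with detection on all 9 arrays (0.0398). Median and mean differed in sign, with no call, for fibroblasts, primordial germ cells, X-linked partners, paternally expressed imprinted genes and glycolysis.

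In total 1358 genes (12.3%) were called between PFGC and oocytes, 882 higher and 476 lower in PFGC, and 383 differed at least 2-fold (347 higher, 36 lower). With the replicate block 2334 genes were called (1346 higher, 988 lower), 1357 of them shared with the 1358. Of the 1358 calls 64.9% were higher, against 31.4% without normalization. The number was sensitive to single arrays: 517 without PFGC replicate 2, 782 without PFGC replicate 3, 561 without oocyte replicate 1, 587 without oocyte replicate 2 and 873 without oocyte replicate 3. Among genes detected on all 9 arrays the lists of undifferentiated (adjusted p = 0.358) and differentiating spermatogonia (0.614), oocyte genes (0.190) and granulosa cells (0.0689) were not called.

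PFGC lay nearer to oocytes than to SSC on the axis between them. PFGC and oocytes were both magnetically sorted and SSC were cultured. Shared handling cannot be told apart from likeness of the cells, here or in the correlation of fold changes below. Over the 3135 genes called at 2-fold or more between oocyte and SSC, the PFGC arrays had positions of 0.800, 0.718 and 0.752, a mean of 0.757 ± 0.041 (SD, n = 3), where 0 is SSC and 1 is oocyte. No p-value is given for the position, because the SSC and oocyte arrays themselves set the axis. Among list members at least 2-fold higher in oocytes, oocyte genes stood at 0.964 ± 0.007, granulosa genes at 0.907 ± 0.034, interferon genes at 0.875 ± 0.028 and endothelial genes at 0.798 ± 0.036. Among members at least 2-fold lower in oocytes, positions were 0.692 ± 0.064 for 19 genes of undifferentiated spermatogonia, 0.444 ± 0.049 for 17 of meiotic prophase and 0.417 ± 0.050 for 16 Sertoli genes (each n = 3). These log-scale positions also depend on the fold between SSC and oocytes. On the linear scale the same genes held SSC shares closer together, 10.5 ± 4.23%, 18.2 ± 5.11% and 15.3 ± 4.05% in that order (SD, n = 3). The 4 genes of undifferentiated spermatogonia and 3 of meiotic prophase that were higher in oocytes stood at 0.859 ± 0.045 and 0.871 ± 0.053, so the position went with the direction of change as well as with the list.

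Fold changes of PFGC and of oocytes against SSC correlated across genes at r = 0.921, where unchanged groups simulated with shared SSC arrays gave 0.530 at most. The covariance was 1.26 against 0.0171 simulated, a difference of 1.24. Genes called in the same direction in both numbered 2496 higher and 2778 lower. The simulated unchanged groups shared at most 1 and 0 by limma, which follows from no gene being changed in them. Independent lists, which leave out the shared arrays, would share 774 and 1013. In all, 7 genes were called in opposite directions. Of the PFGC calls, 92.1% of the higher and 90.8% of the lower were also called in oocytes. With 3 SSC arrays no split of the controls leaves 2 in each part. The simulated part of the shared controls, a covariance of 0.0171, could therefore not be checked on the arrays themselves, and a larger part cannot be excluded. Prl2c2 and Fabp9 lay far from the line of equal change in the plot of fold changes.

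**Figure D2:**
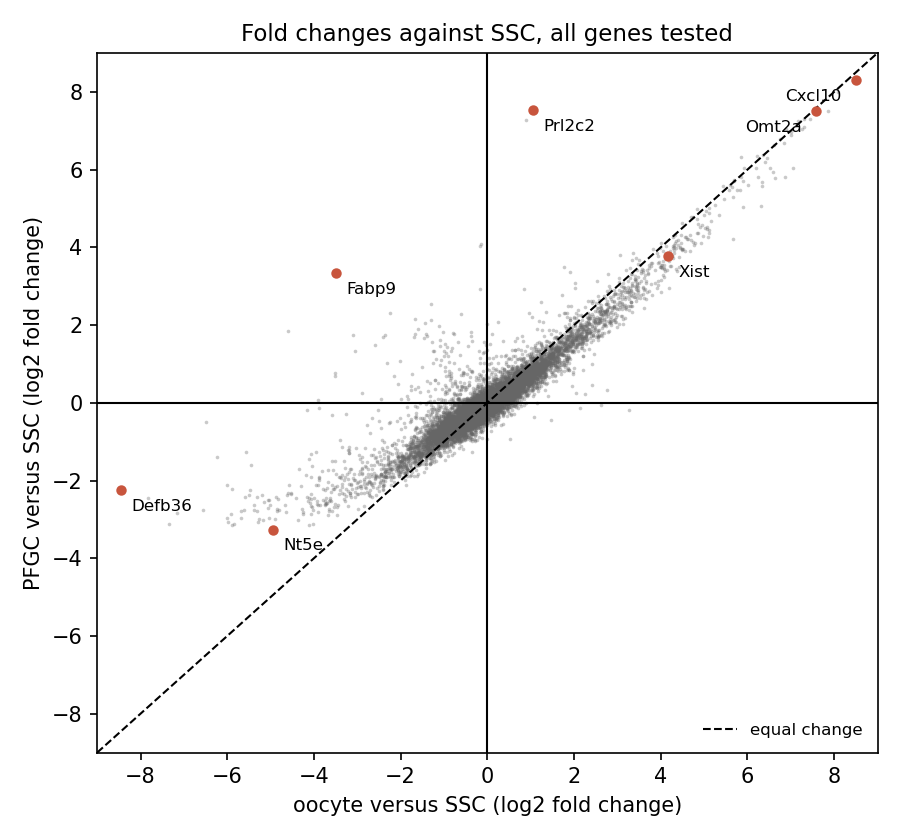
Log2 fold change of each of the 11077 genes in oocyte versus SSC (horizontal axis) and PFGC versus SSC (vertical axis), with the dashed line marking equal change and red points marking labelled genes. Cxcl10, Omt2a and Xist lie near the line, Defb36 and Nt5e changed less in PFGC than in oocytes, and Prl2c2 and Fabp9 lie above the line.

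**Figure D3:**
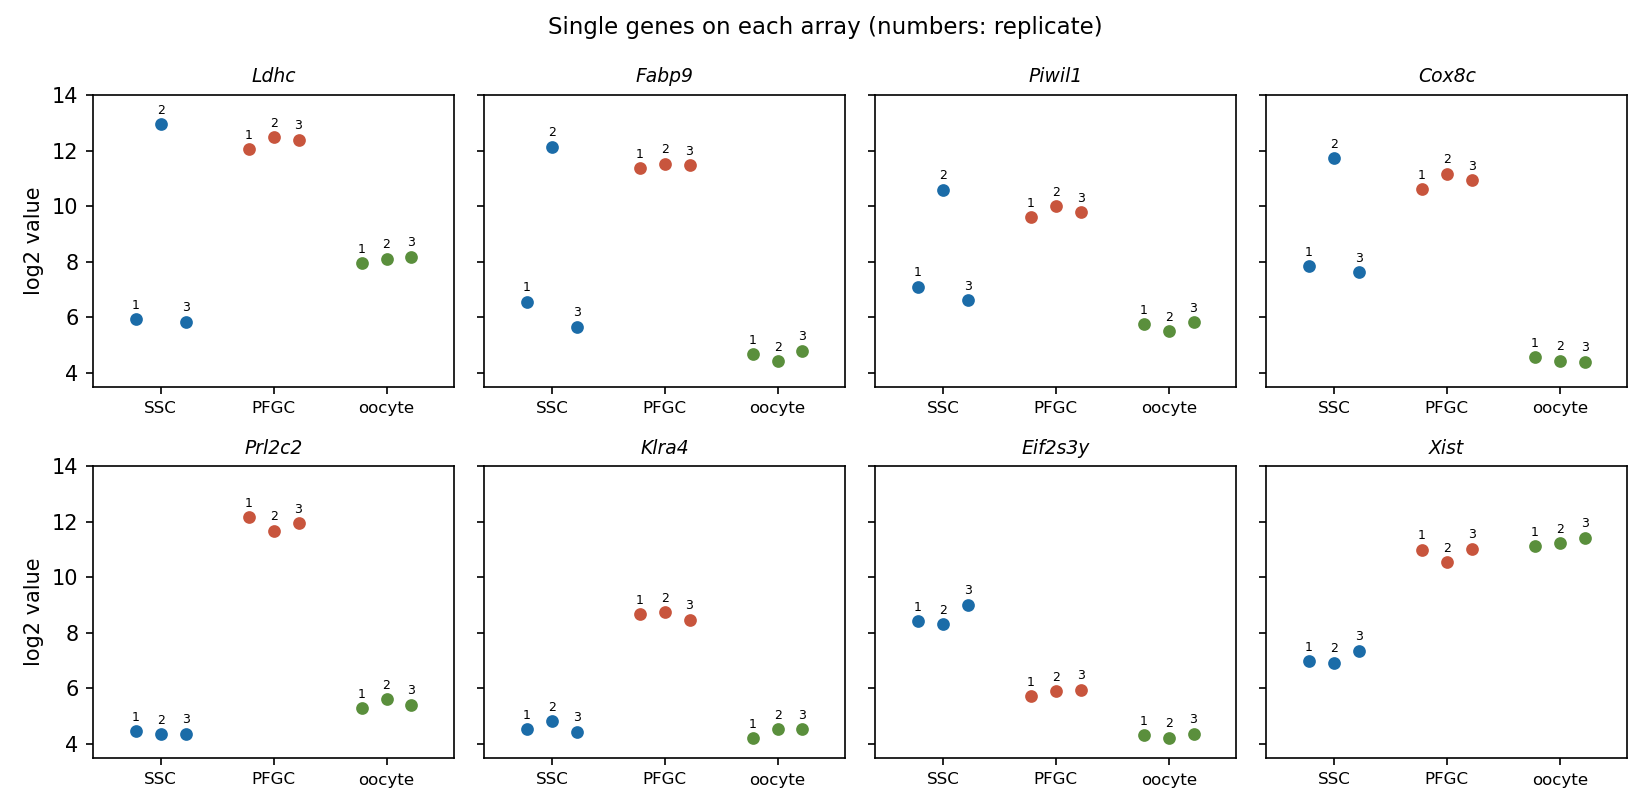
Log2 values of 8 genes on each array, grouped as SSC, PFGC and oocyte, with the replicate number above each point. Ldhc, Fabp9, Piwil1 and Cox8c are high in SSC replicate 2 and in all PFGC arrays, Prl2c2 and Klra4 are high in PFGC alone, Eif2s3y is highest in SSC, and Xist is high in PFGC and oocytes.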

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

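The main calls kept their direction in most alternatives. Of tests on named genes, 8853 stayed on the same side of the threshold, 318 lost the call, 15 gained it and 15 turned direction. Of tests on lists, 2250 kept the call or its absence, 34 lost a call and 44 gained one. Genes called numbered 4394 to 6716 for PFGC versus SSC and 5280 to 7688 for oocyte versus SSC, and with an array left out 4908 to 5784 and 6139 to 6866. For PFGC versus oocyte, leave-one-out counts ran from 517 (without PFGC replicate 2) to 1702 (without SSC replicate 3), array weights gave 2878, and leaving out the arrays numbered 3, a setting added after seeing the data, gave 953. The replicate block gave 6716, 7636 and 2334 genes for PFGC versus SSC, oocyte versus SSC and PFGC versus oocyte, and among the named genes and lists it changed only the calls of the matrix list and Nobox. The PFGC position stayed between 0.736 and 0.777.

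Genes at 2-fold or more numbered 1075, 1597 and 137 with no background correction, in the order PFGC versus SSC, oocyte versus SSC and PFGC versus oocyte. They numbered 1146, 1731 and 159 with the authors' values, and 1257, 1953 and 164 among the 8639 genes detected on all 9 arrays, where fewer genes were tested. An offset of 50 gave 235 for PFGC versus oocyte. The correlation of fold changes was 0.939 among genes detected on all 9 arrays. Apart from the smaller gene set, the cause was not tested.

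Lists called in the same order numbered 2, 2 and 0 by limma's camera with an estimated correlation (at the preset value 16, 21 and 16), and 34, 34 and 32 with fry mixed. Directional fry called 30, 32 and 20. Fry does not set a list against other genes.

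Itga6 turned direction because another of its probes was picked. Its log2 fold changes, -2.62, -3.74 and 1.12 in the same order, became 0.70, 0.83 and -0.13 with detection on all 9 arrays and 0.88, 0.88 and -0.00218 without the arrays numbered 3. With single arrays left out they ran from -2.79 to 0.84, from -3.77 to 0.97 and from -0.13 to 1.33.

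Without normalization the median log2 fold change over all genes was -0.139, 0.083 and -0.239. Several lists with no call then turned the sign of their median, among them pluripotency, DNA methylation, p53 response and cholesterol synthesis in PFGC versus oocyte. A block by array slide was not run because the sources used here give no slide. Since 38.9% to 41.8% of probes were detected per array, the arrays gave no usable level for most probes.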

Other observations

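Genes above both other groups in PFGC were found after the values were seen. In all, 23 genes were called at 2-fold or more above SSC and above oocytes with all 3 PFGC arrays above the 6 others, and 0 were below both by limma. Without adjustment 47 were above both and 0 below. They included Prl2c2, a placental prolactin-family gene also induced in growing fibroblasts, at 11.94 ± 0.25 (SD, n = 3) against 4.40 ± 0.05 in SSC and 5.44 ± 0.17 in oocytes, and its relative Prl2c4 at 11.66 ± 0.21. Klra4, a receptor gene of natural killer cells, stood at 8.63 ± 0.14 against 4.60 ± 0.20 and 4.43 ± 0.19. Medag (8.72 ± 0.08), a gene of fat cell precursors, the mesenchymal transcription factor gene Twist2 (8.51 ± 0.07), Ccl9 (8.07 ± 0.10), the stress-responsive Ankrd1 (7.91 ± 0.12) and the matrix protease gene Mmp3 (7.32 ± 0.27) were lower in both other groups.

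The tests of the 3 patterns below were chosen after the patterns were seen. PFGC arrays lay near the oocyte arrays and showed SSC genes at a lower level. Over 184 genes at least 8-fold higher in SSC than in oocytes, PFGC held a median share of 14.1 ± 3.60% of the SSC signal (SD, n = 3). The oocyte level was subtracted first. RNA like that of these SSC and oocyte arrays alone, mixed in the PFGC samples, could not give the 23 genes above both. SSC or oocyte RNA of another composition was not tested. The absence of genes below both (0) leaves open such a mixture together with RNA of a further source. A single share of RNA like that of these SSC arrays did not hold: at a 2-fold cut, 5 spermatid genes gave a median of 60.0% against 16.1 ± 3.93% for 1511 other genes, above at least 99.6% of random sets matched on fold, and 41.8 ± 7.64% against SSC replicate 2 alone (4 genes, above at least 98.8%), although single genes ran from 8.97% (Hspa1l) to 183% (Fabp9). Granulosa and endothelial genes had a lowest position of 0.757 on any PFGC array. By a prediction written after the values were seen, a change of germ cells alone leaves these genes near the SSC level. They were not near it. Whether the germ cells express these genes was not tested, so this position cannot decide for or against such a change alone. For 4 Y-linked genes the share was 6.82 ± 3.86% (SD, n = 3), with single genes from -0.379% (Kdm5d) to 10.3% (Eif2s3y). Xist in PFGC stood at 76.5% of its oocyte signal. Whether the PFGC RNA came from cells with a Y chromosome was not tested. PFGC and oocytes were magnetically sorted and SSC cultured, and a biological change of germ cells remains possible for the oocyte genes.

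SSC replicate 2 stood apart from the other SSC replicates. In it 76 genes were over 4-fold higher than in the mean of the others and 0 lower, and PFGC held a median of 62.1% of its signal for these genes, oocytes 12.2%. RNA of spermatocytes or spermatids in that sample could account for this: the fixed spermatid list, of which no member is in another list, differed by a median log2 of 1.19, above all 10000 random lists, with Ldhc at 12.96 and Fabp9 at 12.14 in SSC replicate 2. A batch that raised these genes on all arrays numbered 2 does not account for it, as oocyte replicate 2 differed by -0.0416 and PFGC replicate 2 by 0.0918. The labels do not say what the replicate number marks, and a shared batch acting in another way was not tested. An array-wide shift could not be judged, because quantile normalization removes an overall shift before these differences are taken. After it, SSC replicates 1 and 2 differed by a median of 0.163 over all genes, less than the other SSC pairs. Replicates 2 and 3 differed by 0.262, the most of all within-group pairs.

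Some genes of the Sertoli, granulosa, fibroblast and erythrocyte lists had bright probes. Of 23 Sertoli genes, 6 lay in the top 5% on all SSC arrays, against 1.15 expected from the list size. Of 24 granulosa genes, 3 lay there in SSC, 3 in PFGC and 4 in oocytes, against 1.2 expected. Of 40 fibroblast, myoid and feeder genes, 8 lay there in SSC, 10 in PFGC and 9 in oocytes, against 2 expected. No macrophage or endothelial gene lay there in any group. Of 9 erythrocyte genes, 3 lay there in every group, against 0.45 expected. These were the hemoglobin genes Hba-a1, Hbb-bt and Hbb-bs, at log2 levels of 14.17 to 15.19 over the 9 arrays. This rank compares different probes and so decides nothing, and RNA of other gonadal and blood cells in the samples cannot be told apart from expression by the germ cells themselves.

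Regrouping the arrays gave no other split with a called gene, but 10 splits cannot give a share under 0.05. The real grouping was the 1 of 10 with as many calls in each comparison: 5770, 6831 and 1358 genes, against at most 0 by limma in any other split. Without adjustment the counts were 6422, 7266 and 3175, against at most 645, 342 and 1061. If replicate numbers pair the arrays, only splits that part all pairs compare with the real one. The 3 others of this kind gave at most 214, 117 and 171 unadjusted.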
